A study of Mus musculus with 20 samples.

How the data were processed

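Total RNA from the brains of knock-in and wild-type mice was measured on 20 single-channel oligonucleotide arrays whose probe sets carry Affymetrix names. The labels place each array in a genotype, a region (cerebellum or forebrain) and an age. Each genotype and region has 3 arrays at 4 weeks and 2 arrays at the later age, which makes 8 groups. The later age is 11 weeks in the sample descriptions and 12 weeks in the titles, and is called 11 weeks here. The labels conflict about region. For 7 of the 10 arrays grouped as forebrain, all but the 3 of wild-type mice at 4 weeks, the source field and the opening words of the title name cerebellum. For 1 of these 7, knock-in forebrain 4 weeks replicate 3, the description names cerebellum too, while the descriptions of the other 9 name forebrain. All arrays were grouped by the short code in the title, which differs between the regions, so the region of these 7 arrays rests on that code and, for 6 of them, on the description. The labels do not name the knocked-in allele. Nothing in them says that the arrays hold RNA from separate mice, so the p-values measure the spread between these samples, which may be technical. Cerebellum and forebrain arrays may come from the same animals. No scan date was used, so neither age nor genotype can be told apart from any batch that goes with it.

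The deposited values are array intensities on a linear scale, 1 per probe set and array. Their 2% trimmed mean was 2500.59 to 2500.75 on every array, so each array had been scaled to a common mean. The software, its summary of probes and any further normalization are not given in the sources used here. No detection call was used. The table holds 22690 probe sets, of which 64 are array controls. The probe annotation used here names a single gene for 20380 probe sets, several for 691 and none for 1555, controls aside. Of those with a single symbol, 20364 were matched through the Entrez gene number to RefSeq genes of the GRCm38.p6 assembly, and 0 symbols had to be updated. The files name no genome build, so no coordinates are given, and that assembly was used only for names and for which genes neighbour each other.

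Values were tested as log2(intensity + 16). A probe set was kept where its intensity lay above the array's 40th percentile on at least 2 arrays; the median of that limit was an intensity of 681. This kept 15627 probe sets. Each gene was represented by its kept probe set with the highest mean, which gave 9105 genes. The medians of the kept genes spanned 0.12 log2 units over the arrays, under the limit of 0.5 set for renormalizing, so the deposited scaling was kept. Differences are on the log2(intensity + 16) scale, which understates the change of dim genes. Where the dimmer group lay below the filter limit on every array, the size depends on the offset. This held for 8 of 13 and 14 of 26 called and named genes in cerebellum at 4 and 11 weeks, and for 27 of 62 and 18 of 27 in forebrain. Bounds given as at least a fold raise the dimmer values to that limit. No depth exists for arrays, and their number limits the precision.

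A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package, version 1.17.8. It had 12 residual and 3.41 prior degrees of freedom. A gene's adjusted p is from this model, two-sided, with Benjamini-Hochberg adjustment over the genes tested, unless another setting, a left-out array or the list alone is named. That of another probe set is from the same model fitted to all 15627 kept probe sets and adjusted over them, and that of a list is from camera. A gene was called at an adjusted p under 0.05. Errors of log2 differences are standard errors of the model. Errors of intensities are SDs over arrays. The comparisons were knock-in against wild type in each region and age, its mean over ages in each region, its mean over all 4 region and age groups, its difference between regions and between ages, and the wild-type differences between regions and ages. Means over ages weight both ages equally.

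The groups, comparisons, tests, 39 gene lists and the rule for naming genes were fixed before the data were examined. The rule names up to 12 called genes with the largest rise and 12 with the largest fall in each comparison of genotypes, and 8 each way in wild-type comparisons. Where fewer than 10 genes pass, it adds the 5 highest and 5 lowest by p. It also names up to 4 members of a list, by p, where the list is called or where at least 2 members pass. Atxn1, Atxn7 and Igfbp5 are always named. Igfbp5 was included because it had been reported lower in cerebellum in the spinocerebellar ataxias SCA1 and SCA7, perhaps on these same arrays. Of the 39 lists, 36 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and with fry. Fry ended the call of chaperones in cerebellum at 11 weeks (fry adjusted p = 0.3). In forebrain at 11 weeks it ended those of glutamate genes (0.122), immediate early genes (0.324), channels and SCA1 genes (0.0718 each). For the forebrain mean it ended those of glutamate (0.0643) and immediate early genes (0.0909), and between regions that of synaptic vesicle genes (0.0745). A list's calls are also given adjusted over the list alone.

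On simulated data with the real genes and groups (9105 genes, 100 changed at each size), 29% of changes of 0.5 log2 units and 85% of changes of 1 were recovered for cerebellum at 4 weeks. The shares were 14% and 63% for cerebellum at 11 weeks, 39% and 85% for forebrain at 4 weeks, and 14% and 64% for forebrain at 11 weeks. For the means over ages they were 57% and 93% in cerebellum and 55% and 90% in forebrain, and for the difference between regions 18% and 66%. In the simulated forebrain mean, 14 of 159 calls were false.

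The alternatives were quantile normalization, other offsets, filters and thresholds, every probe set tested, trend and robust eBayes, replicate and mouse blocks, array weights, a fit with the compared groups alone, the forebrain array whose description names cerebellum left out, and each array left out in turn. Leaving out an array of a group of 2 leaves a lone array that is assumed to vary like the other groups. Cyclic loess normalization and a larger offset were added after seeing the data. Within groups, arrays correlated at 0.966 to 0.980 over genes, and 0 pairs of arrays held identical values. Over 151 comparisons of named and called genes, wild-type comparisons included, other probe sets of the same gene gave 227 differences. Of these, 200 had the same sign and 27 the opposite sign, and 2 of the 27 passed the threshold.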

Results

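Gene expression was measured in cerebellum and forebrain of knock-in and wild-type mice at 4 weeks (3 arrays per genotype and region) and 11 weeks (2 arrays per genotype and region). Median intensity per array was 979 to 1180. The 3'/5' ratio of GAPDH, a sign of RNA quality, was 0.744 to 0.903 and that of actin 0.934 to 1.23. Between genotypes, the GAPDH ratio was 0.859 ± 0.032 in knock-in and 0.793 ± 0.044 in wild-type forebrain at 4 weeks (SD, n = 3), and 0.876 ± 0.039 against 0.833 ± 0.013 in cerebellum at 11 weeks (n = 2, no overlap). The actin ratio was 0.996 ± 0.088 in knock-in and 1.12 ± 0.04 in wild-type forebrain at 11 weeks (n = 2, no overlap). No exact permutation test within a group this small could pass. The first principal component held 67.7% of the variance and separated the regions. The second held 7.63% and separated the genotypes, with knock-in arrays at 4.67 to 19.5 and wild-type arrays at -20.3 to -3.38. The labels name the region inconsistently for 7 of the 10 arrays grouped as forebrain. These 10 arrays lay at 37.7 to 41.2 on the first component, with knock-in forebrain 4 weeks replicate 3, the array whose description names cerebellum, at 40.2. Pcp2, a Purkinje cell protein, read 50.0 to 579 on them and 38010 to 55244 on the arrays grouped as cerebellum.

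Wild-type cerebellum and forebrain differed in the genes known to mark their cells. Pcp2 was at least 75.8-fold higher in cerebellum (adjusted p = 4.84e-11; a second probe set gave a log2 difference of 3.07), Gabra6, the granule cell GABA receptor subunit, at least 62.4-fold and Cbln3, a granule cell secreted protein, at least 27.3-fold. Bcl11b, a transcription factor of deep-layer cortical and striatal neurons, was at least 7.80-fold higher in forebrain (adjusted p = 6.03e-15), and Camk2a, a kinase of forebrain excitatory synapses, at least 16.9-fold. These 5 lay above the filter limit on 0 of 5 wild-type arrays of the dimmer region, so each fold is a lower bound, taken against that limit. Of the measured granule neuron genes, 17 of 17 were higher in cerebellum, as were 17 of 19 Purkinje cell genes, while 15 of 17 cortical pyramidal neuron genes were lower. Of 17 measured microglia genes 15 were lower in cerebellum, among them C1qa (-1.42), P2ry12 (-1.62) and Csf1r (-1.38). In all, 2496 genes were higher and 2100 lower in cerebellum.

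Igfbp5, a secreted binding protein of insulin-like growth factors, was lower in knock-in mice in both regions. It was named in advance because a fall had been reported, perhaps from these arrays, so its fall here may not be independent of that report. In cerebellum its intensity was 6156 ± 1498 in knock-in and 11042 ± 525 in wild-type mice at 4 weeks (SD, n = 3), and 3666 ± 212 against 9435 ± 261 at 11 weeks (n = 2). In forebrain it was 3544 ± 491 against 6274 ± 548 at 4 weeks and 3686 ± 673 against 6818 ± 1895 at 11 weeks. Every knock-in array lay below every wild-type array of its region and age. The mean of the 4 differences was -0.98 ± 0.10 log2 units, 1.97-fold lower (adjusted p = 4.83e-05). Singly, the adjusted p was 0.0559 and 0.0169 in cerebellum at 4 and 11 weeks, and 0.0122 and 0.0724 in forebrain. The difference between the regions was -0.27 ± 0.20 (adjusted p = 0.748). A second Igfbp5 probe set also had its fitted difference below 0 in each group, from -0.14 in forebrain at 4 weeks to -1.51 in cerebellum at 11 weeks. The Atxn1 probe set read 35.9 to 110 and lay above the filter limit on 0 arrays, so it was not tested. Atxn7 lay above the limit on 8 arrays, and its difference did not pass in any of the 4 groups (smallest adjusted p = 0.357).

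**Figure D1:**
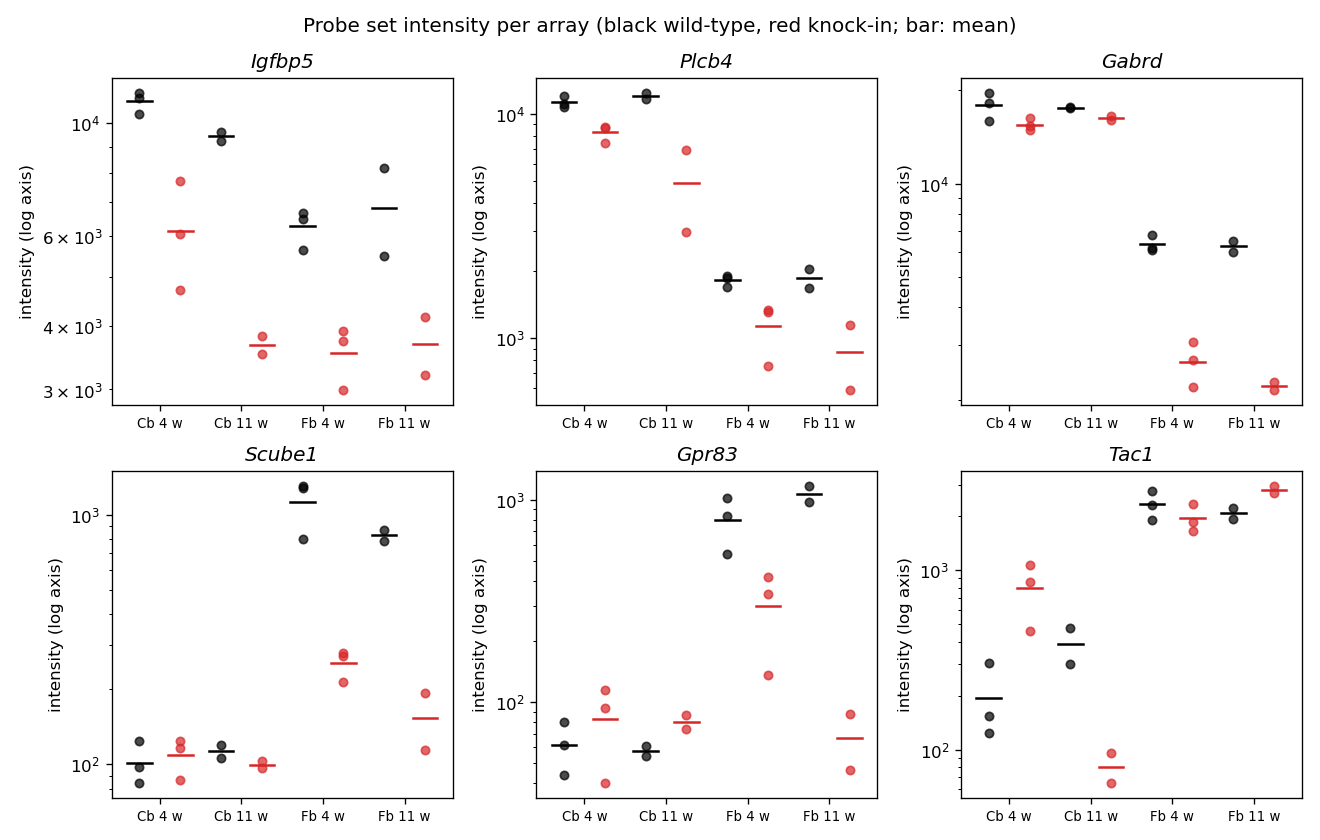
Intensity per array on a log axis for 6 genes, with wild-type arrays in black, knock-in arrays in red and a bar at each group's mean (Cb, cerebellum; Fb, forebrain; 4w and 11w, age in weeks). Igfbp5 and Plcb4 were lower in knock-in arrays of all 4 region and age groups, Gabrd, Scube1 and Gpr83 in forebrain (Scube1 and Gpr83 lay above the filter limit on 0 cerebellar arrays), and Tac1, a dim gene in cerebellum, was higher at 4 weeks and lower at 11 weeks there.

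In cerebellum at 4 weeks, 10 genes were higher and 3 lower in knock-in mice. Leaving out any 1 of the 6 arrays moved this count of 13 by over 1.5 times, from 2 (without knock-in replicate 3) to 78 (without knock-in replicate 2). Of the 13 genes, Anxa2 and Tpd52l1 kept their call without any 1 array. Anxa2, a calcium-dependent membrane-binding protein, rose from 1130 ± 104 to 2596 ± 231 (SD, n = 3), by 1.19 ± 0.15 log2 units (adjusted p = 0.00299). Tac1, the precursor of substance P, rose from 193 ± 95.8 to 797 ± 310 (adjusted p = 0.0188; 0.0722 without wild-type replicate 3), and lay above the filter limit on 0 of the 3 wild-type arrays. S1pr3, a sphingosine-1-phosphate receptor, rose by 1.75, Dysf, a membrane repair protein, by 1.39, and Hoxb2 by 1.01. Tpd52l1 fell by 1.46 (adjusted p = 0.00299), and Fads3, of the fatty acid desaturase family, fell by 1.87. The dimmer genotype of S1pr3, Dysf, Tpd52l1 and Fads3 lay below the filter limit on every array, so these 4 sizes depend on the offset. S1pr3 and Tpd52l1 lay below it on every array of the other genotype too. The 19 measured Purkinje cell genes had a median of -0.17 with 0 past the threshold; the list was called (camera adjusted p = 0.00883), but not with an estimated correlation (adjusted p = 0.0993) or without knock-in replicate 2 (median -0.08, adjusted p = 0.0936). An estimated correlation also ended the call for genes reported lower in the cerebellum of SCA1 (spinocerebellar ataxia type 1) mice. The reports behind that list are not traced here and, as for Igfbp5, may come from these same arrays. The SCA1 list also shares members with the Purkinje cell list, so it is not a separate result. Its median was -0.14 (camera adjusted p = 0.00411, and 0.0993 with an estimated correlation). The same held for the list of polyglutamine disease genes and ataxin-1 partners (median -0.14, camera adjusted p = 0.0359, and 0.0993 with an estimated correlation). Without knock-in replicate 2 their medians were -0.07 and -0.09; the call of the first held (adjusted p = 0.0308), and that of the second was lost without 3 of the 6 arrays (adjusted p up to 0.0835). In the same order, all 3 list calls were lost with quantile normalization (medians -0.10, -0.10 and -0.11; adjusted p = 0.278, 0.35 and 0.278). They were lost too with cyclic loess (adjusted p = 0.0985 for each), where the medians of -0.15, -0.12 and -0.12 lay closer to those of the deposited values. With cyclic loess normalization the genes were 5 higher and 3 lower, and with the arrays of the compared groups alone 0 genes passed (1322 at an unadjusted p under 0.05 in the model of all arrays).

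In cerebellum at 11 weeks, 32 genes were higher and 16 lower in knock-in mice. The GAPDH ratio did not overlap between these knock-in and wild-type arrays. Each of the 26 named genes lost its call without at least 1 array. Cxcl13, a B cell chemokine, rose by 1.44 ± 0.20 (adjusted p = 0.00805), from an intensity of 791 to 2150. Gbp3, an interferon-inducible GTPase, rose by 1.91 and the transcription factors Foxa2 and Sox3 by 2.15 and 1.19. These 3 lay below the filter limit on both wild-type arrays, and Foxa2 and Sox3 on both knock-in arrays too, so their sizes depend on the offset. Tac1, which was higher at 4 weeks, read 80.4 ± 22.2 in knock-in and 388 ± 126 in wild-type mice (SD, n = 2; adjusted p = 0.0338, and 0.09 with the larger offset). All 4 arrays lay below the filter limit and the knock-in mean close to the 10th percentile (mean 70.9), so the size is uncertain. The falls included Sema7a, a membrane-anchored semaphorin (-1.35, adjusted p = 0.018; 0.38 and adjusted p = 0.726 at another probe set), the axon guidance gene Slit1 (-1.42) and Wnt4 (-1.69), both below the filter limit on all 4 arrays and so of uncertain size, and Abcc8, the sulfonylurea receptor of potassium channels (-0.93, adjusted p = 0.01). Kcnip3, a calcium-binding partner of potassium channels, fell by 1.18 (-0.43 and adjusted p = 0.374 at a second probe set), and the T-type calcium channel Cacna1g fell by 0.72 ± 0.14 (adjusted p = 0.0433). The Purkinje cell list had a median of -0.23, with 1 of 19 genes lower and 6 adjusted over the list alone (camera adjusted p = 0.00048; 0.0311 with an estimated correlation). Calcium signalling genes had a median of -0.20 (adjusted p = 0.000818, and 0.0544 with an estimated correlation). Genes of GABA receptors and synthesis had a median of -0.19 (adjusted p = 0.0399, 0.152 with an estimated correlation and 0.073 with cyclic loess, where the median was also -0.19) and chaperones -0.08 (adjusted p = 0.0428, 0.587 with an estimated correlation and 0.154 with cyclic loess, median -0.07), each with 0 members past the threshold. For the GABA list the median was -0.09 and the call lost without knock-in replicate 2 (adjusted p = 0.225) or wild-type replicate 1 (adjusted p = 0.292). The chaperone call was lost without knock-in replicate 1 (adjusted p = 0.201) or wild-type replicate 2 (median -0.06, adjusted p = 0.126), and with quantile normalization (median -0.06, adjusted p = 0.23). Cyclic loess normalization gave 21 higher and 19 lower genes. Without knock-in replicate 2, or with the arrays of the compared groups alone, 0 genes passed (1353 at an unadjusted p under 0.05 in the model of all arrays).

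Averaged over both ages, 307 genes were higher and 135 lower in knock-in cerebellum, and 160 and 143 with cyclic loess normalization. This count of 442 moved by over 1.5 times without 8 of the 10 arrays, to 103 at the lowest (without knock-in 11 weeks replicate 2). Of 33 named genes, 9 kept their call without any 1 array, among them Igfbp5, Kcnip3, Foxa2, Wnt4 and Ctrb1. Purkinje cell genes were lower as a list, with a median of -0.18, 4 of 19 lower, 0 higher and 15 not past the threshold (6 lower adjusted over the list alone; camera adjusted p = 0.00016; 0.0195 with an estimated correlation). The 4 were Plcb4, Cacna1g, Rgs8 and Pcp4. Of these, Plcb4, Cacna1g and Rgs8 also read lower in knock-in forebrain at both ages. Plcb4, the phospholipase C downstream of metabotropic glutamate receptors in Purkinje cells, fell by 0.92 ± 0.22 (adjusted p = 0.0308). Its intensity was 8293 ± 735 against 11259 ± 692 at 4 weeks (SD, n = 3) and 4945 ± 2795 against 11988 ± 508 at 11 weeks (n = 2). Without knock-in 11 weeks replicate 2 the Plcb4 difference was -0.62 (adjusted p = 0.137), and its second probe set gave -0.20 ± 0.17 (adjusted p = 0.522). Cacna1g fell by 0.51 ± 0.09 (adjusted p = 0.00966; 0.0544 without that array), Rgs8, a regulator of G protein signalling, by 0.34 (adjusted p = 0.0257; 0.0922 without it), and Pcp4, a calmodulin-binding protein, by 0.38 (adjusted p = 0.0409; 0.159 without knock-in 11 weeks replicate 1). Pcp2 (-0.10 ± 0.35), Car8 (-0.02 ± 0.13) and Slc1a6 (-0.06 ± 0.10), all abundant in Purkinje cells, did not pass. These errors pool both regions. Pcp2 read 38010 to 55244 on cerebellar arrays but only 50.0 to 579 on forebrain arrays, so its error says little about its spread in cerebellum.

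Among 17 genes reported lower in SCA1 mouse cerebellum, 4 were lower and 0 higher, 7 lower adjusted over the list alone, with a median of -0.18 (camera adjusted p = 3.46e-05; 0.0195 with an estimated correlation). They were Cacna1g, Rgs8, Pcp4 and Icmt, a methyltransferase of prenylated proteins (-0.35, adjusted p = 0.0409; up to 0.119 without 1 array). The list shares its other 3 called genes with the Purkinje cell list and is not independent evidence. Of 27 calcium signalling genes, 3 were lower (Cacna1g, Plcb4 and the ryanodine receptor Ryr1, -0.37, which lost its call whichever 1 of the 10 arrays was left out) and 4 adjusted over the list alone (adjusted p = 0.00142, and 0.0675 with an estimated correlation). Kcnip3 fell by 1.03 ± 0.15 (adjusted p = 0.00336), while its second probe set gave -0.19 ± 0.14 (adjusted p = 0.478). The largest rises were Ctrb1, a digestive protease precursor (2.23), Fosl1 (1.93) and Foxa2 (1.55). These 3 lay below the filter limit on all 10 cerebellar arrays, so their sizes depend on the offset, and 12 of the 12 named rises lay among the dimmest 1821 genes. The lists of granule neurons (median -0.05, adjusted p = 0.366), oligodendrocytes (-0.06, adjusted p = 0.244), microglia (0.14, adjusted p = 0.366) and choroid plexus (-0.10, adjusted p = 0.469) were not called. The Ccnd2 probe sets went both ways, 0.26 and -0.67, and both passed (adjusted p = 0.0436 and 0.0229), while 3 others, from -0.13 to 0.49, did not.

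In forebrain at 4 weeks, 554 genes were higher and 226 lower in knock-in mice, and 262 and 265 with cyclic loess normalization. The GAPDH ratio was higher on average in these knock-in arrays, with overlap. Of 62 named genes, 27 kept their call without any 1 array, among them Gabrd, Gad1, Abat, Tnnc1, Scube1 and Camkk2. Gabrd, the delta subunit of extrasynaptic GABA receptors, fell by 1.27 ± 0.11 (adjusted p = 2.84e-05), from 6374 ± 394 to 2653 ± 440 (SD, n = 3). Tnnc1, a calcium-binding troponin, was lower at 627 ± 117 against 2773 ± 230 (adjusted p = 2.06e-05), as were Scube1, a secreted and cell-surface protein, at 255 ± 36.3 against 1123 ± 283 (adjusted p = 0.000102), the Ras activator Rasgrf2 at 292 ± 15.9 against 1304 ± 109 (adjusted p = 0.00249) and the phosphatase Ptpn4 at 144 ± 30.3 against 882 ± 209 (adjusted p = 2.84e-05). These 4 lay below the filter limit on every knock-in array. Taken against that limit, Tnnc1 was at least 3.66-fold lower, Scube1 1.46-fold, Rasgrf2 1.73-fold and Ptpn4 1.16-fold. Of 12 measured genes of GABA receptors and synthesis, 4 were lower and 0 higher (median -0.24; camera adjusted p = 0.0013, and 0.0608 with an estimated correlation). Besides Gabrd they were Gad1, which makes GABA (-0.65; -0.27 and adjusted p = 0.188 at a second probe set), Abat, which breaks it down (-0.47), and the receptor subunit Gabrb2 (-0.57). Calcium signalling genes had a median of -0.21, with 2 of 27 lower (Camkk2, -0.79, with 0.13 and -0.37 at other probe sets, which did not pass, and Cacna1g, -0.53) and 1 higher (Cacna1c, 0.43; adjusted p = 0.00497, and 0.158 with an estimated correlation). Of 10 measured genes of interferon response and antigen presentation, 2 were higher and 0 lower, with 6 higher adjusted over the list alone (median 0.45; adjusted p = 0.00497, and 0.246 with an estimated correlation). They were the peptide transporter Tap1 (0.67; 0.37 and adjusted p = 0.228 with cyclic loess; adjusted p = 0.0983 without knock-in replicate 2) and the class I gene H2-D1 (0.43; adjusted p = 0.107 without wild-type replicate 2). The 3 other H2-D1 probe sets gave 0.63 (adjusted p = 0.0275), 0.68 (adjusted p = 0.0996) and -1.50 (adjusted p = 0.0401). The microglial genes Laptm5 and Tmem119 rose by 0.60 and 0.46 (other Laptm5 probe sets gave 0.72 and -0.77, adjusted p = 0.304 and 0.393), but the microglia list was not called. The muscarinic receptor Chrm4 rose by 2.14. Tap1 and Chrm4 lay below the filter limit on every wild-type array, so their sizes depend on the offset. With the arrays of the compared groups alone 288 genes passed, and without knock-in replicate 2 there were 318.

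In forebrain at 11 weeks, 50 genes were higher and 51 lower, and 44 and 73 with cyclic loess normalization. The actin ratio did not overlap between these knock-in and wild-type arrays. Of 27 named genes, Gpr83, Scube1, 0610040J01Rik, Ddit4l and Gabrd kept their call without any 1 array. Gpr83, a G protein-coupled receptor, read 66.9 ± 28.8 in knock-in and 1076 ± 133 in wild-type mice (SD, n = 2; adjusted p = 0.000743). The knock-in mean lay below the 10th percentile of those arrays (73.0 and 84.8), so the size is uncertain. Scube1 was lower at 153 ± 55.7 against 825 ± 62.9 (adjusted p = 0.000326) and Rasgrf2 at 269 ± 2.11 against 1428 ± 66.5 (adjusted p = 0.00901). All 3 lay below the filter limit on both knock-in arrays, and taken against that limit they were at least 1.52-fold, 1.17-fold and 2.01-fold lower. Ddit4l, an inhibitor of mTOR signalling, fell by 1.66 (-1.14 and adjusted p = 0.396 at a second probe set), Gabrd by 1.49 ± 0.14 (adjusted p = 0.00015), Kcnip3 by 1.37 (-0.68 and adjusted p = 0.159 at a second probe set) and Rgs8 by 0.80. Sox3, below the limit on both wild-type arrays, rose by 1.35 (adjusted p = 0.00563) and the glutamate transporter Slc1a6 by 0.78. Lists called lower, by median, were cortical pyramidal neuron (-0.35, adjusted p = 0.00191), Bergmann glia and astrocyte (-0.28, adjusted p = 0.000683), calcium signalling (-0.26, adjusted p = 0.000117), glutamate receptors and transporters (-0.23, adjusted p = 0.00915), synaptic vesicle (-0.20, adjusted p = 0.00191) and GABA receptors and synthesis (-0.17, adjusted p = 0.0134). With an estimated correlation the adjusted p of these 6 was 0.0659, 0.0659, 0.056, 0.219, 0.0659 and 0.0693. Also lower were the lists of potassium and sodium channels (-0.19, adjusted p = 0.0278), cerebellar GABAergic interneurons (-0.18, adjusted p = 0.0153), immediate early genes (-0.11, adjusted p = 0.0305) and genes reported lower in SCA1 mouse cerebellum (-0.10, adjusted p = 0.028), with adjusted p = 0.11, 0.0659, 0.319 and 0.165 with an estimated correlation. Each of these 4 lost its call without at least 1 array: channels without knock-in replicate 2 (median -0.06, adjusted p = 0.119) and without either wild-type array (0.053 and 0.0691), interneurons without knock-in replicate 1 (0.0672), immediate early genes without 3 of the 4 arrays (up to 0.307) and SCA1 genes without 2 (up to 0.156). The glutamate and GABA lists lost theirs without wild-type replicate 1 (adjusted p = 0.0558 and 0.0527). The synaptic vesicle median was -0.11 without wild-type replicate 2 and the astrocyte median -0.18 without knock-in replicate 1, with both still called. The immediate early gene median was -0.21 and -0.20 without wild-type replicates 1 and 2, and -0.14 without knock-in replicate 1. With cyclic loess the channel and SCA1 calls were lost (adjusted p = 0.0546 and 0.15), as was the channel call with quantile normalization (adjusted p = 0.06), while the medians stayed near those above: -0.20 and -0.10 with cyclic loess, and -0.19 for channels with quantile normalization. With the arrays of the compared groups alone 9 genes passed, and without knock-in replicate 2 there were 12.

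Averaged over both ages, 940 genes were higher and 489 lower in knock-in forebrain, and 500 and 590 with cyclic loess normalization. Of 93 named genes, 34 kept their call without any 1 array, among them Gabrd, Gad1, Gabrb2, Scube1, Camkk2, Cacna1g, Glul, Mlc1, Itpka, Atn1 and Sparc. Gabrd was 2.61-fold lower (-1.38 ± 0.09, adjusted p = 9.22e-07), Scube1 (adjusted p = 2.91e-06) was lower at an intensity of 214 against 1004, and Rasgrf2 at 283 against 1354. Gpr83 passed too (adjusted p = 0.000125). These last 3 genes lay below the filter limit on every knock-in array, and taken against that limit Scube1 was at least 1.31-fold, Rasgrf2 1.87-fold and Gpr83 1.25-fold lower. For GABA receptors and synthesis, 3 of 12 genes were lower and 0 higher, 4 adjusted over the list alone (median -0.18; camera adjusted p = 0.00146; 0.0465 with an estimated correlation). Gad1 fell by 0.62 ± 0.09 (adjusted p = 0.000904; a second probe set gave -0.19 and adjusted p = 0.201) and Gabrb2 by 0.64. For calcium signalling, 7 of 27 genes were lower and 0 higher, 12 adjusted over the list alone (median -0.26; adjusted p = 0.000164; 0.0465 with an estimated correlation). They included the kinase Camkk2 (-0.89, with -0.41 and -0.53 at other probe sets, which did not pass), Plcb4 (-0.94; -0.70 and adjusted p = 0.0767 without knock-in 11 weeks replicate 2; -0.52 and adjusted p = 0.0522 at a second probe set), the calcium pump Atp2b2 (-0.41) and Cacna1g (-0.44). Of 20 Bergmann glia and astrocyte genes, 4 were lower (median -0.14; adjusted p = 0.00146, and 0.0999 with an estimated correlation). These were glutamine synthetase Glul (-0.53), the membrane protein Mlc1 (-0.57), the acyl-CoA synthetase Acsbg1 (-0.37) and the water channel Aqp4 (-0.36; -0.32 and adjusted p = 0.0742 at a second probe set).

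Among 17 cortical pyramidal neuron genes, 3 were lower in knock-in forebrain over both ages, Rasgrf2, the inositol trisphosphate kinase Itpka (-0.80) and Ier5 (-0.43; -0.32 and -0.01 at other probe sets, which did not pass), and the transcription factor Neurod2 was higher (0.42; median of the list -0.28; adjusted p = 0.00656, and 0.0999 with an estimated correlation). Of 21 immediate early genes, 5 were lower and 1 higher (median -0.11; adjusted p = 0.0198, 0.259 with an estimated correlation and 0.0749 without knock-in 11 weeks replicate 1). The falls included Arc (-0.63), Nr4a1 (-0.59), Dusp1 (-0.58) and Homer1 (-0.58). Of 16 glutamate receptor and transporter genes, 4 were lower and 1 higher (adjusted p = 0.0255, 0.259 with an estimated correlation and 0.0541 with cyclic loess; median -0.24, and -0.29 with cyclic loess), with falls of the NMDA receptor subunit Grin2a (-0.57) and the AMPA receptor subunit Gria3 (-0.46) and a rise of Slc1a6 (0.49). Potassium and sodium channel genes had 2 of 23 lower, Kcna1 (-0.49) and Kcnc1 (-0.63), and 1 higher, Kcnj6 (0.29; 0.33 and adjusted p = 0.182 at a second probe set), with a median of -0.15. Synaptic vesicle genes had a median of -0.07 and 2 of 18 lower, Vamp1 (-0.51; -0.19 and adjusted p = 0.238 at another probe set) and Syt2 (-0.77; -0.32 and -0.22 at other probe sets, adjusted p = 0.128 and 0.261). These lists had adjusted p = 0.0398 and 0.0341, both 0.162 with an estimated correlation. Their calls were lost with quantile normalization (medians -0.15 and -0.05; adjusted p = 0.154 and 0.17), with cyclic loess (medians -0.16 and -0.05; adjusted p = 0.143 and 0.279) and without knock-in 11 weeks replicate 2 (0.0891 for each), and the vesicle median was -0.03 without wild-type 11 weeks replicate 2 (adjusted p = 0.0693). Interferon and antigen presentation genes had 2 of 10 higher, Tap1 (0.65, below the filter limit on every wild-type array) and H2-D1 (0.30). Other H2-D1 probe sets gave 0.42 (adjusted p = 0.0375), 0.26 and -0.78 (adjusted p = 0.393 and 0.119). This list had a median of 0.36 (adjusted p = 0.0198, and 0.162 with an estimated correlation), and of 0.23 with cyclic loess (adjusted p = 0.0557). The lists of cerebellar GABAergic interneurons (3 of 10 lower, adjusted p = 0.0349) and of genes reported lower in SCA1 mouse cerebellum (4 of 17 lower and 1 higher, adjusted p = 0.0337) had adjusted p = 0.148 and 0.162 with an estimated correlation, 0.0778 and 0.226 with cyclic loess, and up to 0.0755 and 0.0632 without 1 array. The interneuron median was -0.15, -0.17 with cyclic loess and -0.08 without wild-type 11 weeks replicate 2, and the SCA1 median -0.09, and -0.07 with cyclic loess. Atn1, atrophin 1, rose by 0.86 (adjusted p = 0.00165) and Sparc, a matrix protein, by 0.56 (adjusted p = 0.00146; 0.22 and adjusted p = 0.223 at a second probe set). The lists of microglia (median 0.06, adjusted p = 0.616), choroid plexus (0.21, adjusted p = 0.454), oligodendrocytes (0.01, adjusted p = 0.965) and striatal projection neurons (-0.05, adjusted p = 0.434) were not called. Without knock-in 11 weeks replicate 2, 551 genes passed.

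**Figure D2:**
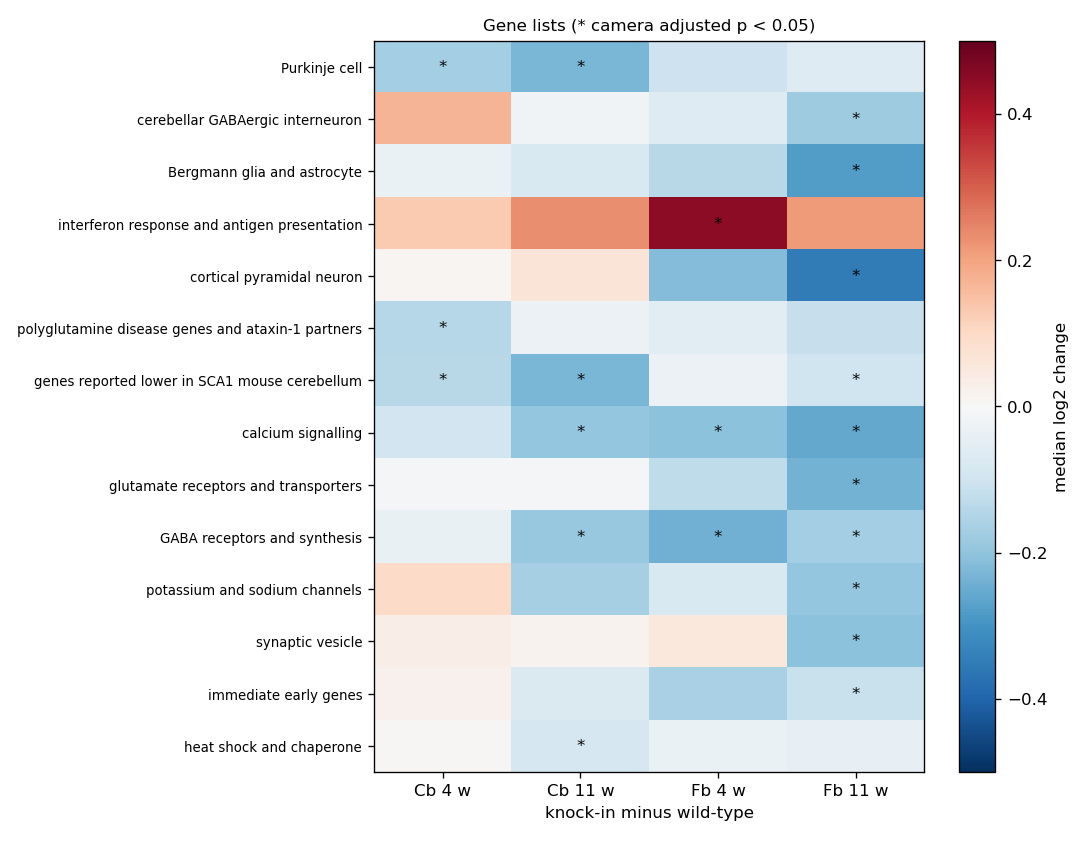
Median log2 difference, knock-in minus wild type, of 14 gene lists (vertical axis) in each region and age (horizontal axis), as colour, with a star where the list's camera adjusted p was under 0.05. Cb is cerebellum and Fb forebrain; stars mark Purkinje cell genes at both ages in cerebellum and calcium signalling and GABA genes at both ages in forebrain, of which only Purkinje cell genes at 11 weeks kept the call with an estimated correlation (adjusted p = 0.0311; 0.0993 at 4 weeks, 0.158 and 0.056 for calcium signalling, 0.0608 and 0.0693 for GABA genes).

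The differences in the 2 regions, measured on different arrays, went together. Across 9105 genes, which are not independent replicates, the cerebellar and forebrain means over ages correlated at r = 0.526 (0.492 with cyclic loess). In both regions 177 genes were higher, against 31.7 for independent lists, 58 were lower, against 7.25, and 4 went opposite ways. The lists are not independent, since the model gives each gene 1 variance for both regions and the arrays may share mice. Both regions also hold the rise of dim genes in knock-in arrays, with medians of 0.19 and 0.22 among the dimmest 1821. The excess over 31.7 and 7.25 thus cannot be read as a shared genotype effect alone. Over all 4 groups, 1542 genes were higher and 822 lower on average, and 912 and 1024 with cyclic loess. Called in 3 of the 4 single groups were Ctrb1 (mean 1.79), Cxcl13 (1.11 ± 0.09, adjusted p = 9.34e-06), Kcnip3 (-1.04), Sox3 (0.96), Treml1 (0.95), Klf3 (0.87), Sfmbt2 (0.77) and Gm33301 (0.75). Klf3 was chosen after its values were seen, and its other probe sets gave -0.58 and -0.20 (adjusted p = 0.0881 and 0.0899), the opposite sign. A second Kcnip3 probe set gave -0.32 (adjusted p = 0.0309). The falls largest on average were Rrp9 (-1.63), Alas2, which starts haem synthesis (-1.46), Krtap3-1 (-1.45), Mcm6, a DNA replication helicase subunit (-1.39), and Shroom3 (-1.37). Ctrb1 and Sfmbt2, on every wild-type array, and Rrp9, Krtap3-1, Mcm6 and Shroom3, on every knock-in array, lay below the filter limit, so their sizes depend on the offset. Of the 12 largest rises and the 12 largest falls, 11 each lay among the dimmest 1821 genes.

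**Figure D3:**
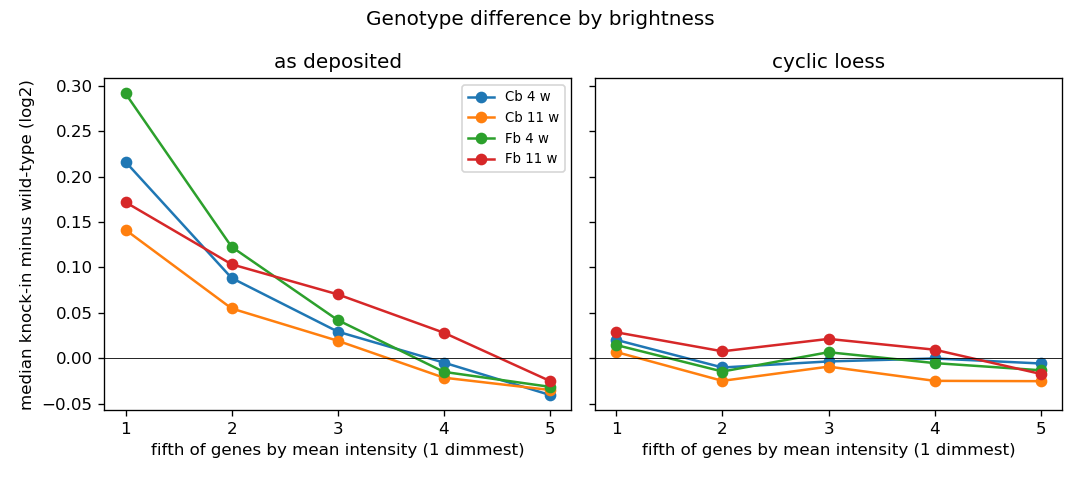
Median log2 difference, knock-in minus wild type, of genes in 5 equal groups by mean intensity (horizontal axis, dimmest to brightest), 1 line per region and age (Cb, cerebellum; Fb, forebrain), for the deposited values (left) and after cyclic loess normalization (right). Averaged over the 4 groups, the dimmest group lay at 0.21 and the brightest at -0.03 in the deposited values, and at 0.02 and -0.01 after cyclic loess.

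The genotype difference itself differed between the regions for 48 genes, 33 higher and 15 lower in cerebellum than in forebrain. Fewer passed where arrays with the same replicate number were treated as blocks, as given in the section on processing. Of the 33, 30 were called lower in forebrain. Of these 30, 19 lay above the filter limit on all 5 wild-type cerebellar arrays, 4 on some of them and 7 on 0 cerebellar arrays of either genotype. The 7 were Gpr83, Scube1, Rasgrf2, Csmd1, Tnnc1, Myl4 and Ddit4l, with mean intensities in wild-type cerebellum from 48.3 (Rasgrf2) to 407 (Tnnc1), where a fall was hard to measure, so their difference between regions says little about cerebellum. Gabrd, among the 19, fell in forebrain and was -0.16 in cerebellum (mean intensity 15819 in knock-in and 17780 in wild-type mice), a difference between regions of 1.23 ± 0.13 (adjusted p = 0.000323). The histamine receptor Hrh3 differed by 1.31 (adjusted p = 0.00259). Camkk2 differed by 0.72 (adjusted p = 0.039; 0.46 and 0.65 at other probe sets, which did not pass), and Igfbp4, a second binding protein of insulin-like growth factors, by 0.81 (adjusted p = 0.0246; other probe sets gave 0.64 to 1.54, of which 2 of 5 passed). The ciliary dynein Dnah11 differed the other way (-2.12, adjusted p = 0.0246; 0.0824 without knock-in cerebellum 11 weeks replicate 2), as did the histone demethylase Kdm3b (-1.25) and the Hedgehog-pathway transcription factor Gli1 (-1.03). Dnah11 and Gli1 lay above the limit on 0 forebrain arrays. The lists of cortical pyramidal neurons (median 0.22, adjusted p = 0.0068), synaptic vesicle genes (0.12, adjusted p = 0.015) and GABA genes (0.14, adjusted p = 0.0151) were among those called, with adjusted p = 0.119, 0.145 and 0.119 with an estimated correlation. The cortical median was moved by over 1.5 times, to larger values, without 10 of the 20 arrays. Without knock-in cerebellum 11 weeks replicate 1 the vesicle and GABA calls were lost (adjusted p = 0.072 for each). Of the 24 named genes, 15 kept their call without any 1 array. Without knock-in forebrain 11 weeks replicate 2, 22 genes passed.

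**Figure D4:**
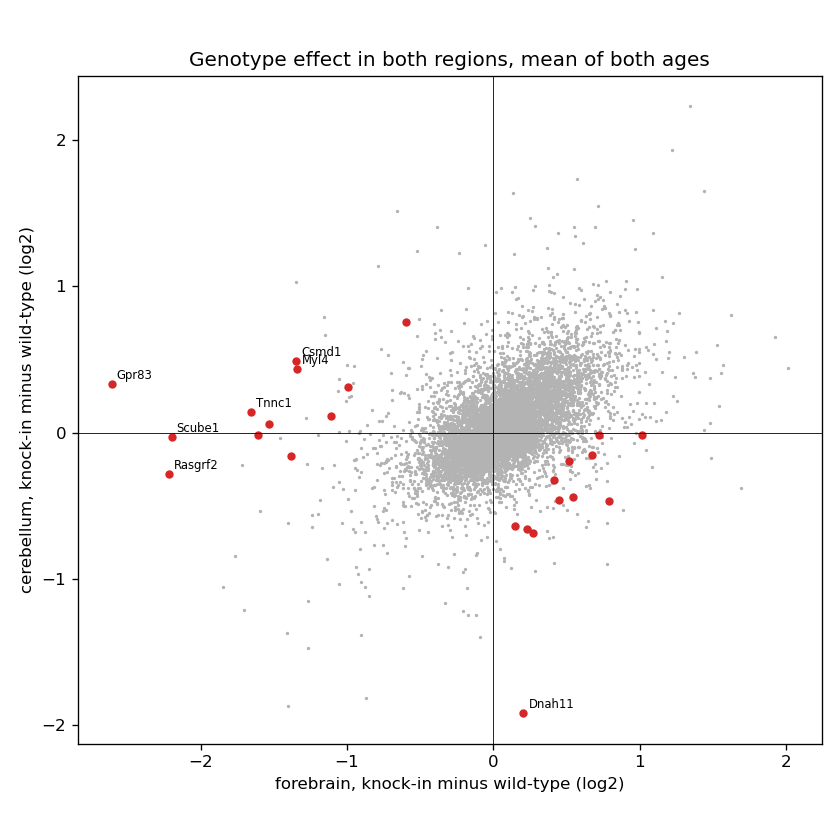
Log2 difference, knock-in minus wild type, averaged over ages, in forebrain (horizontal axis) and cerebellum (vertical axis), 1 point per gene. Red points are the 24 named genes whose difference between regions passed the threshold, and names are given for some of them; Gpr83, Scube1, Rasgrf2 and Tnnc1 lie far to the left but were above the filter limit on 0 cerebellar arrays, so their place on the vertical axis is not a measured lack of change.

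Between ages, the genotype difference changed for 2 genes in cerebellum and 0 in forebrain (limma; 516 and 586 genes at an unadjusted p under 0.05). Tac1 (adjusted p = 0.00526) went from higher at 4 weeks to lower at 11 weeks, but lay above the filter limit on only 2 of the 10 cerebellar arrays, both from knock-in mice at 4 weeks, so its size is uncertain. D430019H16Rik differed by -2.29 (adjusted p = 0.00856; 0.0611 without knock-in 11 weeks replicate 2), a size that is uncertain too, since it lay above the limit on 1 of these 10 arrays. With the arrays of the compared groups alone 0 genes passed. In forebrain the nearest to passing was Msn, moesin, a linker of membrane and actin (0.97, adjusted p = 0.0981), whose second probe set gave -0.01 ± 0.32 (adjusted p = 0.999). With quantile or cyclic loess normalization 0 genes passed there too.

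In wild-type mice, 4 genes were higher and 14 lower at 11 than at 4 weeks in cerebellum. Slit1 rose by 1.45 and Nbl1, a BMP antagonist, by 1.08, while Cd160 fell by 2.28 (adjusted p = 0.00381), the collagen gene Col3a1 by 1.85, and gelsolin (Gsn), an actin-severing protein, by 1.38 (adjusted p = 0.00723; 0.0587 without 11 weeks replicate 2; -1.95 and adjusted p = 0.125 at 1 of its 3 other probe sets). The dimmer age of Slit1, Cd160 and Col3a1 lay below the filter limit on every array, so their sizes depend on the offset. The 2 wild-type cerebellar arrays at 11 weeks also enter the genotype difference at 11 weeks, with the opposite sign. A rise with age here and a fall in knock-in mice there, as for Slit1, are thus not separate results. Of 12 named genes, 2 kept their call without any 1 array. Oligodendrocyte and myelin genes had a median of -0.67, with Gsn as the 1 called member and 10 lower adjusted over the list alone (camera adjusted p = 2.71e-14, and 0.105 with an estimated correlation). In wild-type forebrain, the 1 called gene was Msn (-0.90, adjusted p = 0.00352; 0.0659 without 11 weeks replicate 1), whose second probe set gave -0.00 ± 0.22 (adjusted p = 0.998). The difference between ages in the genotype effect of Msn, given above, used the same wild-type forebrain arrays with the opposite sign, so it is not a separate result. With the arrays of the compared groups alone, 0 genes passed in either region.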

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

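The test of forebrain blocks with fallen genes kept in the lists of forebrain parts, the repeats of the Purkinje cell test without each gene and its counting of mirror-image relabellings once, the count of fallen genes above the filter limit in cerebellum, and the use of cyclic loess as a normalization were chosen only after the results they bear on were seen. Counts of other splits of the arrays were planned.

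The genotype difference differed between cerebellum and forebrain, by the model's own test of that difference, for 24 named genes. On the log2(intensity + 16) scale, the model's fitted value of cerebellum minus forebrain was 2.94 for Gpr83, 2.17 for Scube1, 1.94 for Rasgrf2, 1.84 for Csmd1, 1.80 for Tnnc1, 1.78 for Myl4, 1.59 for 0610040J01Rik, 1.59 for Ddit4l, 1.36 for Ttc19, 1.31 for Hrh3, 1.23 for Gabrd and 1.22 for Stard8. It was -2.12 for Dnah11, -1.25 for Kdm3b, -1.03 for Gli1, -0.99 for Rnf19b, -0.96 for Mus81, -0.91 for Lpar1, -0.89 for Resf1, -0.83 for Adamts10, -0.79 for Dcaf4, -0.74 for Dpf2, -0.74 for Ppp4c and -0.71 for Mroh1. Of these, Gpr83, Scube1, Rasgrf2, Csmd1, Tnnc1, Myl4 and Ddit4l lay above the filter limit on 0 of 10 cerebellar arrays, and Dnah11, Gli1 and 0610040J01Rik on 0 of 10 forebrain arrays, so for these 10 the fitted value is not a measured size. A second Rnf19b probe set gave 0.15 (adjusted p = 0.9). The fitted difference between ages in cerebellum was -2.29 for D430019H16Rik and -4.02 for Tac1, which lay above the filter limit on 1 and 2 of 10 cerebellar arrays, so these values are not measured sizes either. Among probe sets with no single gene name, 319 of 1217 kept (26.2%) passed for the mean of the 4 groups, against 3382 of 14410 with a name (23.5%). No group holds 4 to 10 arrays, so no single array was tested as standing apart.

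Other splits of the same arrays bear on the counts of called genes. For the mean of the 4 groups, 1 of 100 splits, the real one, reached 2364 genes; the highest other gave 1774 and differed from the real split by 1 exchanged pair of 4-week cerebellar arrays. For the means over ages, 1 of 60 splits reached the real count in cerebellum (442, highest other 47) and 1 of 60 in forebrain (1429, highest other 67). For wild-type regions 1 of 60 did (4596, highest other 964). If the arrays are independent samples, chance can be excluded at the 0.05 level for these counts. The labels do not show that they are, and the splits of the mean of the 4 groups relabelled each region separately. If arrays share mice, these splits cannot exclude a chance difference between a few mice. For the difference between regions, 2 of 100 splits reached 48 genes; the other gave 410, kept every cerebellar label and turned most forebrain labels, so it measured the genotype difference that both regions share, which is a structure of these samples. At 4 weeks the 10 splits are too few for a share under 0.05: cerebellum gave 13 genes against 4 at most in another split, and forebrain 780 against 8.

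More genes were higher than lower in knock-in arrays, most of all among dim genes, where 515 were higher and 69 lower among the dimmest 1821. Of the calls for the mean of the 4 groups 65.2% were higher, and 47.1% after cyclic loess, as a difference between arrays that depends on intensity would give; a true rise of many dim genes would be removed by loess too, so the skew itself is not evidence of biology. A higher background on knock-in arrays might underlie it: 27 non-mouse control probe sets were higher by 0.191 ± 0.128 (two-sided exact permutation p = 0.119), above the 0.104 set in advance as needed for the dim shift but not past the threshold, so this cannot be told apart. By group the controls differed by 0.23 and -0.01 in cerebellum at 4 and 11 weeks and by 0.46 and 0.09 in forebrain. The 10th percentile of intensity, which the dim genes themselves can move, was higher in knock-in arrays in each group, at 82.9 against 66.4 and 70.9 against 64.6 in cerebellum at 4 and 11 weeks, and 87.7 against 69.2 and 78.9 against 72.9 in forebrain.

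The second pattern is 30 genes that were called lower in knock-in forebrain, not in cerebellum, and differed between the regions; 7 of them lay above the filter limit on 0 cerebellar arrays, so a fall there was hard to measure, and 19 lay above it on all 5 wild-type cerebellar arrays. After cyclic loess 29 of the 30, and 19 of those 19, still passed for the difference between regions. The trend with intensity raised dim genes of knock-in arrays in both regions, by medians of 0.19 and 0.22 among the dimmest 1821. Its removal could hardly end calls of a fall in 1 region, so this result says little about the cause. Forebrain blocks that held less cortex in the knock-in mice could lower genes of that part. The cortical list had a median of -0.284, short of the bound of -0.425 set at 0.5 times the median fall of the 30 genes (-0.851). The standard error of the mean over its 17 genes, 0.152, reaches from that median to the bound. It measures the spread between genes, not between arrays, so it cannot decide, and this cause cannot be told apart. A biological difference between forebrain and cerebellum stays open and untested.

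The third pattern is the lower Purkinje cell genes in knock-in cerebellum. A trend with intensity does not account for it, since the median of the list was -0.164 after cyclic loess against -0.179 before. A lower share of Purkinje cell RNA would lower genes restricted to these cells alike. The 9 genes tested were those at least 2 log2 units higher in wild-type cerebellum than forebrain. That does not show that Purkinje cells alone express them within cerebellum. Their differences ranged from -0.92 (Plcb4) to -0.02 (Car8), with an SD of 0.283. The same SD in residuals, over 60 relabellings, had a median of 0.156 and a highest value of 0.204 (permutation p = 0.0167, the smallest these can give), and p was 0.0167 without any 1 of the 9 genes; without Plcb4, whose second probe set gave -0.20, the SD was 0.169 against a median of 0.0745. The 9 genes thus did not fall alike. Genes that other cerebellar cells also express would fall unequally under an equal loss, so this cannot decide whether Purkinje cell RNA was lost. The model's standard errors of Pcp2 (0.35) and Ppp1r17 (0.36), which pool both regions, are larger than most of these differences. Plcb4, Cacna1g and Rgs8 also read lower in knock-in forebrain at both ages, with no overlap of arrays. At 4 weeks Plcb4 read 1133 ± 330 there against 1817 ± 104 in wild-type mice (SD, n = 3). The falls of these genes were thus not confined to cerebellum, and whether they arise in Purkinje cells was not tested.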

How the results depend on the processing

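Cyclic loess normalization and a larger offset were chosen after seeing the data. The next counts pool all comparisons and include genes not called in either fit, so they overstate how firm the genotype calls are. Wild-type cerebellum against forebrain has 143 named and called genes, and the genotype comparison in cerebellum at 4 weeks has 13. Of those 13, 2 kept their call without any 1 array. Over all settings, named genes kept their direction and side of the threshold in 14425 cases, lost the call in 1412 and gained one in 188. In 28 the sign changed without passing. For gene lists these counts were 3758, 161 and 86, with 314 changes of sign without passing and 1 reversed: the oxidative phosphorylation list in cerebellum at 11 weeks without knock-in replicate 2 (adjusted p = 0.0263), with a median of -0.11, where leaving out each array gave adjusted p values from 0.00872 (without knock-in replicate 1, median 0.13) to 0.982. The cause of the changes below was not tested, except where fewer arrays or genes entered. Signal over background limits dim genes, whose changes the offset of 16 shrinks, and the small number of arrays limits the single-age comparisons.

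Called genes (13, 48, 780 and 101 for cerebellum at 4 and 11 weeks and forebrain at 4 and 11 weeks; 442 and 1429 for the cerebellar and forebrain means; 2364 for the mean of all 4; 48 for the difference between regions; 2 and 0 for the difference between ages in cerebellum and forebrain; 4596 between wild-type regions; 18 and 1 between wild-type ages in cerebellum and forebrain) moved by over 1.5 times as follows. Quantile normalization gave 276 for the cerebellar mean and 2 for wild-type forebrain ages. Cyclic loess gave 8 for cerebellum at 4 weeks and 2 for wild-type forebrain ages, as did the larger offset for the latter (2). With no filter there were 8 and 12 for cerebellum at 4 and 11 weeks, 53 for forebrain at 11 weeks, 270 for the cerebellar mean, 21 between regions and 2 for wild-type forebrain ages. A filter at the 60th percentile gave 1 between ages in forebrain. Testing every probe set gave 8 for cerebellum at 4 weeks, 3701 for the mean of all 4, 4 between ages in cerebellum, 7485 between wild-type regions and 31 for wild-type cerebellar ages. Trend and robust eBayes gave 32 and 94 for cerebellum at 4 and 11 weeks and 35 for wild-type cerebellar ages. A threshold of 0.1 gave 101, 184, 1525 and 240 for the 4 single groups, 898 and 2278 for the means over ages, 1 between ages in forebrain and 33 for wild-type cerebellar ages. Array weights gave 54 and 160 for cerebellum at 4 and 11 weeks, 709 for the cerebellar mean and 42 for wild-type cerebellar ages. With the arrays of the compared groups alone there were 0 and 0 for cerebellum at 4 and 11 weeks, 288 and 9 for forebrain, 0 between ages in cerebellum and 0 and 0 for wild-type ages. Without the forebrain array whose description names cerebellum cerebellum at 4 weeks gave 8.

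Leaving out each array in turn gave 2 (without knock-in replicate 3) to 78 (without knock-in replicate 2) for cerebellum at 4 weeks, 0 (without knock-in replicate 2) to 22 (without wild-type replicate 1) for cerebellum at 11 weeks, 318 (without knock-in replicate 2) to 802 (without wild-type replicate 1) for forebrain at 4 weeks, and 12 (without knock-in replicate 2) to 67 (without wild-type replicate 2) for forebrain at 11 weeks. The cerebellar mean gave 103 (without knock-in 11 weeks replicate 2) to 471, the forebrain mean 551 (without knock-in 11 weeks replicate 2) to 1517, the mean of all 4 1702 to 2437, and the difference between regions 22 (without knock-in forebrain 11 weeks replicate 2) to 47. The difference between ages gave 1 to 5 in cerebellum and 0 to 3 in forebrain, wild-type regions 4072 to 4514, and wild-type ages 10 (without 4 weeks replicate 1) to 30 in cerebellum and 1 to 7 in forebrain. The count moved by over 1.5 times for 6 of 6, 4 of 4, 4 of 6 and 4 of 4 arrays in the 4 single groups in this order, 8 of 10 in the cerebellar mean, 2 of 10 in the forebrain mean, 0 of 20 in the mean of all 4 and 6 of 20 between regions.

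Whether the replicate numbers pair the samples stays open. Deviations of same-numbered arrays from their group means were correlated. Between genotypes of a region, r was -0.0914 to 0.0306 over 6 pairs at 4 weeks and 0.00992 to 0.0698 over 4 at 11 weeks. Between regions of a genotype it was -0.0366 to 0.112 and 0.0639 to 0.0845, with 1 pair over 0.1. Each group at 11 weeks has 2 arrays, so deviations mirror each other and pairs of a kind repeat values. Differently numbered arrays were not used as a reference, so these correlations cannot rule out shared mice. With the number as a fixed replicate block there were 31 genes between regions, 33 for wild-type cerebellar ages and 9 for wild-type forebrain ages, and with a block by genotype, age and number 23 between regions; other counts stayed within 1.5 times. A random mouse block had a consensus correlation of 0.0514.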

Other observations

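The test of neighbouring genes was planned, and the groupings of clock and growth factor genes come from lists fixed before the data were examined.

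Of 16 measured circadian clock genes, 1 was higher and 2 lower in knock-in cerebellum and 1 higher and 3 lower in forebrain, means over ages, beside 442 and 1429 called among all 9105 genes. The list was not called in either region (adjusted p = 0.429 and 0.167, and 0.772 and 0.3 with an estimated correlation). Clock, the transcription factor that drives the daily cycle, fell by 0.43 ± 0.08 in cerebellum (adjusted p = 0.0143) and by 0.32 in forebrain (adjusted p = 0.023). Without knock-in 11 weeks replicate 2 of each region these adjusted p values were 0.0693 and 0.109, and a second Clock probe set gave -0.31 and -0.28 (adjusted p = 0.215 and 0.194). Per1, which represses that factor, rose by 0.39 and 0.35 (adjusted p = 0.0441 and 0.0349, and up to 0.156 and 0.169 without 1 array). Npas2, a relative of Clock, was -0.82 in cerebellum (adjusted p = 0.0432), with all 10 cerebellar arrays below the filter limit, but 0.21 at its other probe set (adjusted p = 0.654). Bhlhe40 fell by 0.82 in forebrain (adjusted p = 0.0108; 0.061 without wild-type 11 weeks replicate 1) and Hlf by 0.46, with -0.33 at a second Hlf probe set (adjusted p = 0.0569). The labels give no time of day.

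Of 17 measured genes of the insulin-like growth factor axis, 3 were lower and 2 higher in knock-in forebrain over both ages, and the list was not called (median 0.08, adjusted p = 0.287). The binding proteins Igfbp5 (-0.85; -0.38 and adjusted p = 0.404 at a second probe set), Igfbp4 (-0.49; from -1.30 to -0.42 at 5 others, of which 3 passed) and Igfbp6 (-0.42) fell, and the adaptor Grb10 rose by 0.40 (other probe sets gave -0.07 and -0.03, neither past the threshold). Among neuropeptide genes of the forebrain, 4 of 18 were lower, with falls of Vip (-0.72) and Bdnf (-0.49), and 2 were higher, Nts (0.56) and Pcsk1n (0.53), the last an inhibitor of prohormone processing (adjusted p = 0.0341 for the list, 0.19 with an estimated correlation, 0.105 with quantile normalization, 0.0778 with cyclic loess and up to 0.13 without 1 array). The median of that list was -0.18, with -0.16 after quantile normalization and -0.17 after cyclic loess. It was -0.11 without wild-type 4 weeks replicate 1, and also without knock-in 11 weeks replicate 1.

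Intensity of Xist, the RNA of the inactive X chromosome, was 7232 to 20410 on the 20 arrays, and that of the Y-linked Eif2s3y 3.03 to 108. Ttr, a choroid plexus transcript, ranged from 1086 to 25269 over forebrain arrays and from 39451 to 104928 over cerebellar arrays.

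A hypothesis for genes that changed in the same direction in all 4 knock-in groups is a stretch of chromosome from another mouse strain carried with the knock-in allele, which could place called genes side by side. Of 9098 genes in their order along the chromosomes, 156 were called at an adjusted p under 0.001, and the fullest window of 20 neighbouring genes held 4 of them. Of 1000 random orders, a share of 0.42 held a window as full, and their 95th percentile was 4, so these values give no sign of such a stretch as the source of the pattern.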
